A study of Homo sapiens with 14 samples.

How the data were processed

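The series measured gene expression in HEL cells, a human erythroleukemia line that takes on megakaryocyte features when treated with the phorbol ester TPA. Cells carried either a control plasmid (control/HEL) or a doxycycline-inducible MKL1 insert (MKL1/HEL), and were kept for 24 hours with or without TPA and with or without doxycycline. Total RNA was hybridised to 10 Affymetrix arrays covering all 8 combinations. Only MKL1/HEL cells with TPA had 2 arrays in each doxycycline state, and the other 6 groups had 1 array each. The same 4 RNA samples of the duplicated groups were also hybridised to 4 Illumina arrays, so these are a technical repeat on another platform and not further replicates. Groups and replicate numbers were taken from the sample titles. Nothing in the labels says that replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

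Affymetrix values were deposited on the log2 scale after RMA, per the submitters' processing notes, with no version given. They cover 54675 probe sets, and the sorted columns of the 10 arrays differ by at most 0.00343, so the arrays share one distribution. The Illumina value table of 22177 probes holds, as deposited, log2 values whose powers of 2 are all whole numbers, and array medians from 6.67 to 6.88, so no normalization between arrays had been applied. The bead summary files, made with BeadStudio 3.1 per the submitters' processing notes, give intensity on a linear scale. In these deposited files the columns were shifted against the header by a number that differed between files, and together they held the signals of 2 arrays, namely MKL1/HEL with TPA with and without doxycycline, replicate 1 of each. For these, 99.98 percent of value table entries equalled the rounded signal. A detection p-value was likewise deposited for those arrays alone, so the design's fallback was used for Illumina: normexp background correction with an offset of 50, then quantile normalization between arrays, from the value table. On the array without doxycycline, 55.1 percent of bead types had a detection p under 0.01. Background and summary settings of the upstream software are not given in the sources used here.

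Probes were named through the platform annotation tables. On Affymetrix 41097 probe sets had 1 gene symbol, 1801 had several and 11777 had none. On Illumina 19708 probes had 1 symbol and 2469 had none. Probes with several symbols or none were left out. Entrez identifiers of 41043 and 19688 probes matched the RefSeq gene table of assembly GRCh38, which was used only for symbols, and no coordinates are given. A gene was represented by the probe with the highest mean on its platform. Genes were tested if they lay above the 40th percentile of the array on at least 2 arrays, which left 15208 of 19775 genes on Affymetrix and 11000 of 16577 on Illumina. Arrays give no read depth, and the number of arrays limits the precision.

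Tests used limma 3.58.1 in R 4.3.3 with empirical Bayes moderation, two-sided, and Benjamini-Hochberg adjustment over all genes tested, with a threshold of adjusted p under 0.05. Figures were drawn with Python 3.11.15. Comparisons of doxycycline or of the lines on Affymetrix came from 1 fit of all 10 arrays with 8 group means. It has 2 residual degrees of freedom, all from the duplicated groups, and single arrays were assumed to vary like those. The SD across genes of the difference between duplicates was 0.382 with doxycycline and 0.373 without. That of single arrays with and without doxycycline was 0.118 in control/HEL without TPA, 0.13 in control/HEL with TPA and 0.151 in MKL1/HEL without TPA. Tests on single arrays thus borrowed a spread wider than the whole difference between them. TPA was tested over all 10 arrays, 6 with and 4 without, in a model with a term for each of the 4 combinations of line and doxycycline and 5 residual degrees of freedom. The Illumina fit used its 4 arrays. Platforms were compared by correlations across genes, which are not independent replicates.

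The groups, designs, gene lists, naming rule and most alternatives were fixed before the data were examined. MKL1 was named first. For MKL1 induction with TPA and for TPA treatment, the 10 largest rises and the 10 largest falls that passed were named, and for each other comparison the 5 largest in each direction. Where fewer than 5 passed, the genes of smallest unadjusted p filled the places and are said not to pass. From gene lists, 2 to 4 members with the smallest p were named, and any other named gene was chosen after its values were seen. The 21 lists, written from general knowledge, covered SRF and MRTF cytoskeletal targets, immediate early genes, megakaryocyte and platelet genes, erythroid genes, markers of monocytes, lymphocytes, and fibroblasts or endothelium, mitosis, DNA replication, p53 targets, NF-kB targets, AP-1 and phorbol ester response, interferon response, cholesterol synthesis, the ATF4 response, oxidative phosphorylation, ribosome biogenesis with MYC targets, the unfolded protein response, heat shock, hypoxia and integrins. Lists were tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry, each adjusted over the 21 lists. The count of members passing is given over all genes tested and adjusted over the list alone.

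The fits were tested on simulated data, with 200 genes of known change per comparison in 20 draws. With gene variances drawn from the fitted prior, MKL1 induction with TPA on Affymetrix recovered 8.5 percent of genes changed by 1 on the log2 scale, 86.9 percent of those changed by 2 and 99.0 percent of those changed by 4. Illumina recovered 47.8, 96.3 and 99.7 percent, and MKL1 induction without TPA 0.4, 49.4 and 96.9 percent. For TPA, 34.0 percent of genes changed by 0.5, 88.3 percent of those changed by 1 and 98.0 percent of those changed by 2 were recovered. Between 4.77 and 5.17 percent of calls were false. With each gene's own moderated variance, recovery of a change of 1 was 63.5, 90.4, 13.6 and 93.0 percent in the same order of comparisons. The false share was then 8.47, 8.43, 8.61 and 4.82 percent, so the nominal 5 percent was exceeded in the fits with 2 residual degrees of freedom.

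The alternatives were no filter, a 60th percentile filter, the mean of all probes of a gene, median centring, quantile normalization of the deposited values, an intensity trend with robust moderation, the replicate number as a block, leaving out each array in turn, other sets of arrays, a 1.5-fold minimum, and for Illumina no background correction with an offset of 16, scaling to the same median, and the deposited values unchanged. The 60th percentile filter on Illumina, TPA treatment without the MKL1/HEL doxycycline arrays, and the lists without each duplicated array were added after seeing the data. A filter on detection on all 4 Illumina arrays was not run, because detection p-values were at hand for 2 arrays.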

Results

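Gene expression was measured in HEL cells, an erythroleukemia line with both erythroid and megakaryocyte traits, that carried a doxycycline-inducible MKL1 insert (MKL1/HEL) or a control plasmid (control/HEL). MKL1, also called MRTFA, is a coactivator of the transcription factor SRF. TPA is a phorbol ester that activates protein kinase C and drives these cells toward the megakaryocyte lineage. On Affymetrix arrays, MKL1/HEL cells treated with TPA had 2 arrays with doxycycline and 2 without. The other 6 combinations of line, TPA and doxycycline had 1 array each, so their differences have no replicate of their own. All 10 arrays had the same median of 6.03 and the same range from 3.32 to 14.84 on the log2 scale. The 4 Illumina arrays held the same RNA samples as the duplicated groups and had median signals of 102, 105, 118 and 102. The comparisons asked what MKL1 induction and TPA each changed, alone and together.

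The level of MKL1 itself was read first. On the Affymetrix probe set with the highest signal MKL1 differed by -0.62 with doxycycline in TPA-treated MKL1/HEL cells and by 0.24 in those without TPA, the latter on 1 array against 1. With TPA the arrays read 8.45 and 9.39 without doxycycline and 8.20 and 8.40 with it. The size of the fall thus depends on the second array without doxycycline. In control/HEL cells the same probe set differed by 0.02 with TPA and by -0.09 without. Its other 4 probe sets differed by -0.26, -0.21, -0.13 and 0.13 with TPA in MKL1/HEL cells and by -0.06 to 0.23 without, and the Illumina probe for MKL1 by -0.06 with TPA. Whether these probes lie within the insert is unknown, so the values do not measure how much MKL1 was induced.

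The largest rises with MKL1 induction in TPA-treated cells included genes of the smooth muscle cytoskeleton. TAGLN, an actin-binding protein of smooth muscle, rose by 6.74 on the log2 scale (SE 0.23, 107-fold, adjusted p = 0.000964). ACTA2, smooth muscle alpha-actin, rose by 6.08 (SE 0.25, 67.8-fold, adjusted p = 0.00127), although 1 of its 3 probe sets differed by -0.01. RPE65, an isomerase of the retinal visual cycle, rose by 6.37 (SE 0.23, adjusted p = 0.000964), and SPRR2C, of a family of cornified envelope genes with closely similar sequences, rose by 6.36 (SE 0.19, adjusted p = 0.000964). PLN, the phospholamban gene that regulates the calcium pump of muscle, rose by 4.24 (SE 0.17, adjusted p = 0.00127). The remaining genes among the 10 largest rises were TPRG1 (5.55, adjusted p = 0.0133), the matrix protein tenascin C gene TNC (5.19, adjusted p = 0.0228), the chemokine gene CXCL11 (5.06, adjusted p = 0.0310), the neuroligin gene NLGN1 (4.54, adjusted p = 0.00718) and the cathepsin G gene CTSG (4.22, adjusted p = 0.00557). Of 15208 genes tested, 85 rose and 4 fell. Those that fell were the sialyltransferase gene ST3GAL6 (-1.98, SE 0.24, adjusted p = 0.0417), TINAG (-1.94, SE 0.18, adjusted p = 0.0210), the cell cycle phosphatase gene CDKN3 (-1.44, SE 0.18, adjusted p = 0.0437) and the collagen receptor subunit gene ITGA2 (-1.21, SE 0.16, adjusted p = 0.0498). IKZF2, at -1.38, did not pass (adjusted p = 0.0719), but did with an intensity trend (0.00970) and without the first array with doxycycline (0.00952). All 89 genes changed at least 2-fold, and in all 89 both arrays with doxycycline lay beyond both without, which selection on these same arrays favours. At an unadjusted p under 0.05 there were 904 genes higher and 755 lower, with 760 expected by chance in all.

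**Figure D1:**
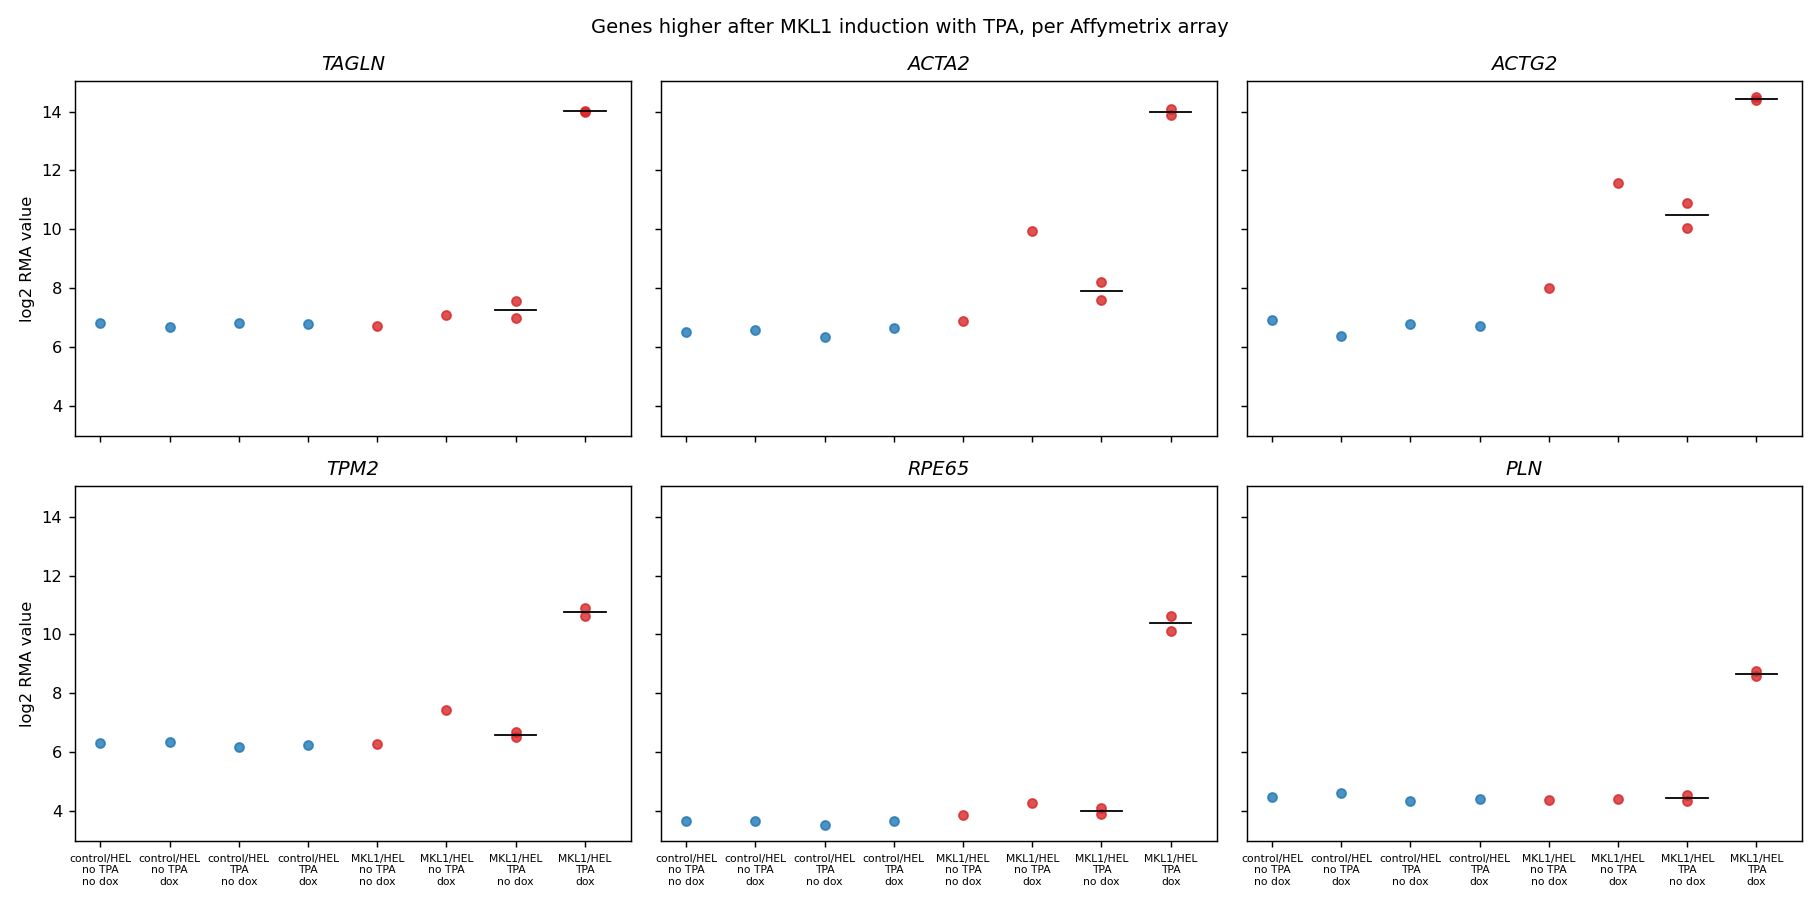
Log2 RMA value (vertical axis) of 6 genes on each of the 10 Affymetrix arrays, by line, TPA and doxycycline (dox, horizontal axis), where each point is an array, blue for control/HEL and red for MKL1/HEL, and the black line is the mean of duplicates. All 6 are highest in MKL1/HEL cells with TPA and doxycycline, and ACTA2, ACTG2 and TPM2 are also above their untreated level in MKL1/HEL cells with doxycycline alone, on 1 array.

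The number of genes passing depended on few arrays. Without the first array of TPA-treated MKL1/HEL cells lacking doxycycline 10 genes passed, and without the second 8. Without the first array with doxycycline, 363 genes rose and 282 fell. With no filter on low values 28 rose and 1 fell, and TPRG1, TNC, CXCL11, ST3GAL6, CDKN3 and ITGA2 no longer passed (adjusted p from 0.0563 to 0.0893). TNC and CXCL11 also failed with an intensity trend (adjusted p = 0.0535 and 0.0729), as did ITGA2 (adjusted p = 0.0593), and TNC, ST3GAL6 and ITGA2 with the mean of all probe sets (adjusted p = 0.0869, 0.0757 and 0.126). TAGLN, RPE65, SPRR2C, ACTA2 and PLN passed with either of the arrays lacking doxycycline left out. TPRG1 (adjusted p = 0.118 and 0.192), TNC (0.148 and 0.234), NLGN1 (0.0692 and 0.112), CTSG (0.0678 and 0.0873), ST3GAL6 (0.148 and 0.323), TINAG (0.0906 and 0.192), CDKN3 (0.141 and 0.302) and ITGA2 (0.191 and 0.338) failed without the first and without the second of these arrays, and CXCL11 without the second (0.112). CDKN3 (adjusted p = 0.0548) and ITGA2 (0.0998) also failed without the second array with doxycycline. With the 6 MKL1/HEL arrays in a single comparison over both TPA states, 1 gene passed and the named genes did not (adjusted p = 0.771 to 0.774). That comparison fits 1 doxycycline effect to both TPA states, so a response seen only with TPA adds to its residual spread. TAGLN, for instance, differed by 6.74 with TPA and by 0.38 without, so this count does not show a dependence on few arrays. An intensity trend gave 173 genes. Of the 85 genes that rose, 25 had a mean without doxycycline under the 40th percentile of the array, 5.46, where values are near background. Among them were RPE65, SPRR2C, TPRG1, TNC, CXCL11, NLGN1 and PLN, so the sizes and order of their rises depend on the background level.

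Among SRF and MRTF cytoskeletal targets, 6 of 30 measured genes rose with MKL1 induction under TPA, and none fell. Besides TAGLN and ACTA2 these were the tropomyosin genes TPM2 (4.16) and TPM1 (1.57), the gamma-smooth muscle actin gene ACTG2 (3.97) and the caldesmon gene CALD1 (3.95). ACTG2 had a mean of 14.44 with doxycycline, close to the array maximum of 14.84, so the size of its rise may be limited. Adjusted over the list alone 13 rose, and the list's median difference was 0.59 (camera adjusted p = 2.87e-16; adjusted p = 0.517 with an estimated correlation). In megakaryocyte and platelet genes, GP5, a subunit of the von Willebrand factor receptor, rose (3.90, adjusted p = 0.0210) and ITGA2 fell, while 28 of 30 did not pass. Adjusted over the list alone 1 rose and 2 fell (camera adjusted p = 0.243). None of 28 erythroid genes passed limma over all genes or adjusted over the list alone (unadjusted 1 higher and 4 lower, camera adjusted p = 0.617). Mitosis genes were lower in all 31 members, with a median of -0.94 (camera adjusted p = 5.95e-21; adjusted p = 0.517 with an estimated correlation). None of them passed limma over all genes, 25 were lower at an unadjusted p under 0.05, and 23 fell when adjusted over the list alone, among them BUB1 (-1.01), MKI67 (-1.33) and AURKB (-1.02). DNA replication genes were negative in all 34 members, with a median of -1.03 (camera adjusted p = 2.51e-13; adjusted p = 0.517 with an estimated correlation), and included RRM2 (-1.20) and RRM1 (-1.02). None passed limma over all genes or adjusted over the list alone, and 12 were lower unadjusted. This median was -0.28 in the first replicate and -1.71 in the second, and it was -0.30 without the second doxycycline array and -1.75 without the first. With an estimated correlation no list of this comparison kept its call.

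**Figure D2:**
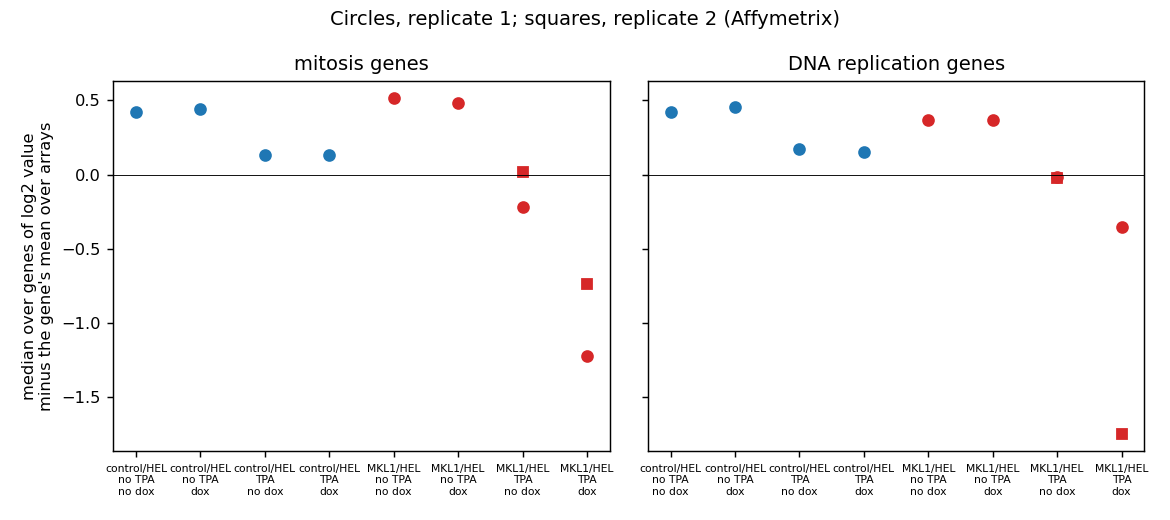
Median over the genes of a list of the log2 value minus the gene's mean over arrays (vertical axis) on each Affymetrix array by line, TPA and doxycycline (horizontal axis), for 31 mitosis genes and 34 DNA replication genes, with circles for replicate 1, squares for replicate 2, blue for control/HEL and red for MKL1/HEL. In MKL1/HEL cells with TPA and doxycycline the mitosis medians are -1.22 and -0.74, and the DNA replication medians are -0.35 and -1.75.

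Other lists were read for the same induction. Immediate early genes had a median of 0.48, with 0 of 17 passing limma over all genes or adjusted over the list alone and 4 higher unadjusted (camera adjusted p = 5.01e-05; adjusted p = 0.540 with an estimated correlation; 0.0750 without the first array lacking doxycycline). AP-1 and phorbol ester response genes had a median of 0.41, 0 of 16 passing over all genes, 3 higher unadjusted, and 3 that rose when adjusted over the list alone, namely TIMP3 (1.70), MMP9 (2.53) and JUN (1.65). The camera adjusted p of that list was 0.000201, with 0.134 without the first array lacking doxycycline and adjusted p = 0.555 with an estimated correlation. Interferon response genes had a median of 0.24 and 0 of 21 passing over all genes, with 5 higher unadjusted and 4 that rose adjusted over the list alone, among them ISG15 (1.33) and IFI6 (1.44). The median of these 21 genes was 0.03 in the first replicate and 0.47 in the second. Their camera adjusted p was 0.000696, with 0.302 without the second array lacking doxycycline and adjusted p = 0.517 with an estimated correlation. Ribosome biogenesis and MYC target genes had a median of -0.45, with 0 of 21 passing over all genes or adjusted over the list alone and 5 lower unadjusted (camera adjusted p = 2.28e-06; adjusted p = 0.517 with an estimated correlation). That median was -0.17 in the first replicate and -0.75 in the second, and -0.05 and -0.71 on Illumina. Cholesterol synthesis genes had a median of -0.39, with 0 of 19 passing either way and 4 lower unadjusted (camera adjusted p = 0.00164; adjusted p = 0.517 with an estimated correlation; 0.0624 without the first array lacking doxycycline). The p53, NF-kB and hypoxia lists each held a gene that rose over all genes and adjusted over the list alone, without a camera call: TIGAR (1.93) of 15 p53 target genes (camera adjusted p = 0.154), the chemokine gene CCL4 (9.85-fold) of 19 NF-kB target genes (0.617) and the collagen prolyl hydroxylase gene P4HA2 (4.13) of 23 hypoxia genes (0.617). Among 18 integrin genes ITGA2 fell, and 2 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.709).

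Markers of other cell types were also read for MKL1 induction with TPA. Fibroblast and endothelial genes differed between platforms, with medians of 0.16 and -0.15 in the first and second replicate on Affymetrix. On Illumina these were 0.41 and 0.41. The counts and tests that follow are from Affymetrix. By limma over all genes 0 of 16 monocyte, 0 of 14 lymphocyte and 0 of 10 fibroblast and endothelial genes passed, with 1, 1 and 3 higher and 0, 0 and 1 lower unadjusted. Adjusted over the list alone, IL7R (2.43) rose among lymphocyte genes and PDGFRA (2.66), COL1A2 (0.96) and THY1 (0.71) among fibroblast and endothelial genes. The camera adjusted p values were 0.851, 0.705 and 0.115, and the last was 0.0257 without the second array lacking doxycycline and 0.0180 without the second array with it. In the ATF4 response (23 genes), unfolded protein response (16), oxidative phosphorylation (27) and heat shock (10) lists 0 genes passed limma over all genes or adjusted over the list alone. Unadjusted counts were 2 lower, 2 lower, 1 higher, and 1 higher with 1 lower. Camera adjusted p was 0.0616, 0.0616, 0.617 and 0.511, and the first pair was 0.0408 and 0.0349 without the second doxycycline array.

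On Illumina the same RNA samples showed 141 genes that rose and 31 that fell with MKL1 induction, of 11000 tested, with 1133 higher and 1032 lower at an unadjusted p under 0.05 and 550 expected in all. TAGLN rose by 6.57 (SE 0.20, adjusted p = 0.000826), ACTA2 by 5.52 (SE 0.27, adjusted p = 0.00343), TPM2 by 4.32 (SE 0.14, adjusted p = 0.000826), RPE65 by 5.18 (SE 0.40, adjusted p = 0.0160) and SPRR2F, a paralog of SPRR2C, by 5.61 (SE 0.22, adjusted p = 0.00183). TNC (4.14), NLGN1 (2.86) and CTSG (4.05) also rose, whereas TPRG1 (1.30, adjusted p = 0.205), CXCL11 (2.93, adjusted p = 0.0599) and PLN (1.04, adjusted p = 0.0701) did not pass. The largest falls were the heparanase gene HPSE (-2.02, adjusted p = 0.0355), the crystallin gene CRYBA4 (-1.55, adjusted p = 0.0368), ST3GAL6 (-1.47, adjusted p = 0.0471), the ribosomal protein gene RPS15 (-1.39, adjusted p = 0.0264) and RFX6 (-1.38, adjusted p = 0.0427). ITGA2 fell (-1.15, adjusted p = 0.0300), and TINAG (-0.52, adjusted p = 0.158) and CDKN3 (-1.21, adjusted p = 0.0540) did not pass. On Affymetrix RPS15 had means of 14.44 without and 14.33 with doxycycline, close to the array maximum of 14.84, where a probe set can be saturated and a fall go unseen. In all 172 genes both arrays with doxycycline lay beyond both without, which selection on these same arrays favours. With either of the arrays lacking doxycycline left out 0 genes passed limma, without the first array with doxycycline 1404 did, and without the second ST3GAL6 had an adjusted p of 0.0540. With no background correction ST3GAL6 (adjusted p = 0.0622) and RFX6 (0.0501) failed, and with the mean of all probes ST3GAL6 failed (0.0508).

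The balance of rises and falls on Illumina moved with the scaling of the arrays. With each array scaled to the same median 78 genes rose and 57 fell, and the median of the genes tested was -0.13. On the deposited values, without correction or normalization, 272 rose and 806 fell around a median of -0.21. An intensity trend gave 262 genes. The SRF and MRTF list kept a positive median, 0.89 over 31 genes and 0.65 and 0.57 under those scalings, with 7 genes higher over all genes and 23 adjusted over the list alone (camera adjusted p = 1.76e-16; adjusted p = 0.550 with an estimated correlation). Mitosis genes had a median of -0.87 (-1.06 and -1.13 under the scalings), with 0 of 31 passing limma over all genes, 22 lower unadjusted and 19 that fell adjusted over the list alone (camera adjusted p = 1.58e-13; adjusted p = 0.550 with an estimated correlation). DNA replication genes had a median of -0.88 (-1.12 and -1.19), with 0 of 34 passing over all genes, 11 lower unadjusted and 3 that fell adjusted over the list alone (camera adjusted p = 3.82e-08; adjusted p = 0.550 with an estimated correlation). Under quantile normalization their median was -0.20 in the first replicate and -1.62 in the second. In megakaryocyte and platelet genes GP5 (3.07) and P2RX1 (1.09) rose and ITGA2 fell. Lists with a positive median about as large as the shift of all genes or smaller changed sign with the scaling. Medians under quantile normalization, the same median and the deposited values were 0.22, 0.06 and -0.02 for interferon response genes, 0.20, -0.03 and -0.11 for monocyte genes, 0.07, -0.14 and -0.22 for integrin genes, and 0.04, 0.01 and -0.07 for lymphocyte genes. For p53 target genes they were 0.0047, -0.02 and -0.10.

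Across the 10021 genes tested on both platforms, the log2 fold changes had a Pearson correlation of 0.805 and a Spearman correlation of 0.693, a description across genes, which are not independent replicates. Of 77 shared genes that passed on Affymetrix, 76 had the same sign on Illumina, and of 165 that passed on Illumina, 161 had the same sign on Affymetrix. There were 44 genes that rose on both platforms and 2, ST3GAL6 and ITGA2, that fell on both. Independent lists of these sizes would share 0.976 and 0.0124 genes, but both platforms read the same RNA.

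**Figure D3:**
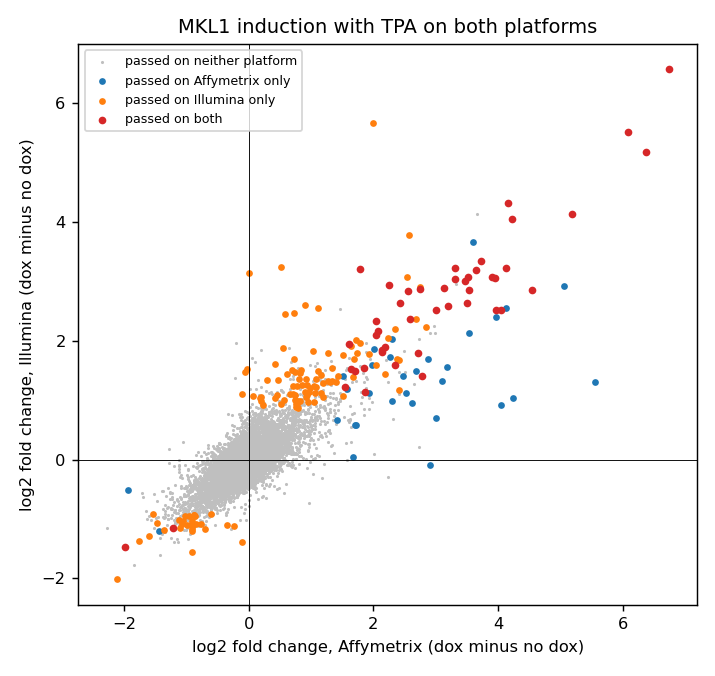
Log2 fold change with doxycycline in TPA-treated MKL1/HEL cells on Affymetrix (horizontal axis) and on Illumina (vertical axis), where each point is 1 of 10021 genes, coloured by whether it passed on neither, on 1 or on both platforms. The genes that passed on both lie in the quadrants of equal sign, 44 higher and 2 lower.

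TPA treatment changed 3395 of 15208 genes, and KLF1 and EPB42 of the erythroid list had the largest falls. GZMB, the granzyme B gene, rose by 7.57 (SE 0.40, 191-fold, adjusted p = 1.41e-05). RGS13, a regulator of G protein signalling, rose by 5.71 (SE 0.17, 52.5-fold, adjusted p = 1.05e-06), PHLDA1 by 5.39 (SE 0.09, 42.0-fold, adjusted p = 7.83e-08) and the transporter gene SLC12A8 by 5.01 (SE 0.12, adjusted p = 2.83e-07). The other genes among the 10 largest rises were the protease inhibitor gene A2M (5.23), FCGR1BP (5.12), the surface receptor genes CD93 (4.45) and CD300C (4.34), the histone deacetylase gene HDAC9 (4.32) and the kinase gene SGK1 (4.30). The largest fall was that of KLF1, the erythroid master transcription factor (-3.78, SE 0.12, adjusted p = 1.06e-06), followed by EPB42, a protein of the red cell membrane skeleton (-3.50, SE 0.28, adjusted p = 0.000119). ID4 (-3.47), the interferon-induced RSAD2 (-3.39), IGFBP5 (-3.29), the iron exporter gene SLC40A1 (-3.17), NPY1R (-3.04), the erythroid nuclear protein gene HEMGN (-3.04), MS4A3 (-2.78) and FREM1 (-2.74) also fell. In total 1549 genes rose and 1846 fell, of which 501 and 259 changed at least 2-fold, and 3388 of the 3395 had the same sign in all 4 combinations of line and doxycycline. Selection on these same arrays favours equal signs. At an unadjusted p under 0.05 there were 5169 genes. Of the genes that rose, 71 had a mean without TPA under the 40th percentile of the array, 5.46, among them GZMB, RGS13, SLC12A8, FCGR1BP, CD93 and HDAC9, so the sizes and order of their rises depend on the background level. Of the genes that fell, 38 had a mean with TPA under that level, among them NPY1R and MS4A3, whose falls are limited by it. Fitting 8 group means gave 1774 genes and control/HEL arrays alone 5508. The count was 1938 without the MKL1/HEL array lacking TPA and doxycycline, and 2244 without either of the control/HEL arrays with doxycycline, whose lone partner then carries no information. Of the 3395 genes, 981 rose and 854 fell by at least 1.5-fold. Without the MKL1/HEL doxycycline arrays, an alternative chosen after seeing the data, 1412 rose and 1574 fell, and 2614 were shared.

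Megakaryocyte and platelet genes rose as a group with TPA. Of 30 measured, 14 rose, among them ITGA2 (2.92), the P-selectin gene SELP (2.02) and the cyclooxygenase gene PTGS1 (1.46), while NFE2 (-1.38) and TUBB1 (-0.91), a transcription factor and a tubulin of platelet formation, fell. Adjusted over the list alone 16 rose and 3 fell, with a median of 0.41 (camera adjusted p = 7.12e-06; adjusted p = 0.0355 with an estimated correlation). Of 28 erythroid genes 16 fell, among them KLF1, EPB42 and RHAG (-1.99), and CA2 (1.11) rose. Adjusted over the list alone 17 fell and 1 rose, with a median of -0.59 (camera adjusted p = 6.91e-08; adjusted p = 0.0355 with an estimated correlation). NF-kB target genes rose in 15 of 19 members over all genes and adjusted over the list alone, and 1 fell. Their median was 1.37, with IL6 at 2.70, CXCL8 at 3.62 and NFKBIA at 1.36 (camera adjusted p = 1.98e-11; adjusted p = 0.0409 with an estimated correlation). These 3 lists alone kept their call with an estimated correlation.

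**Figure D4:**
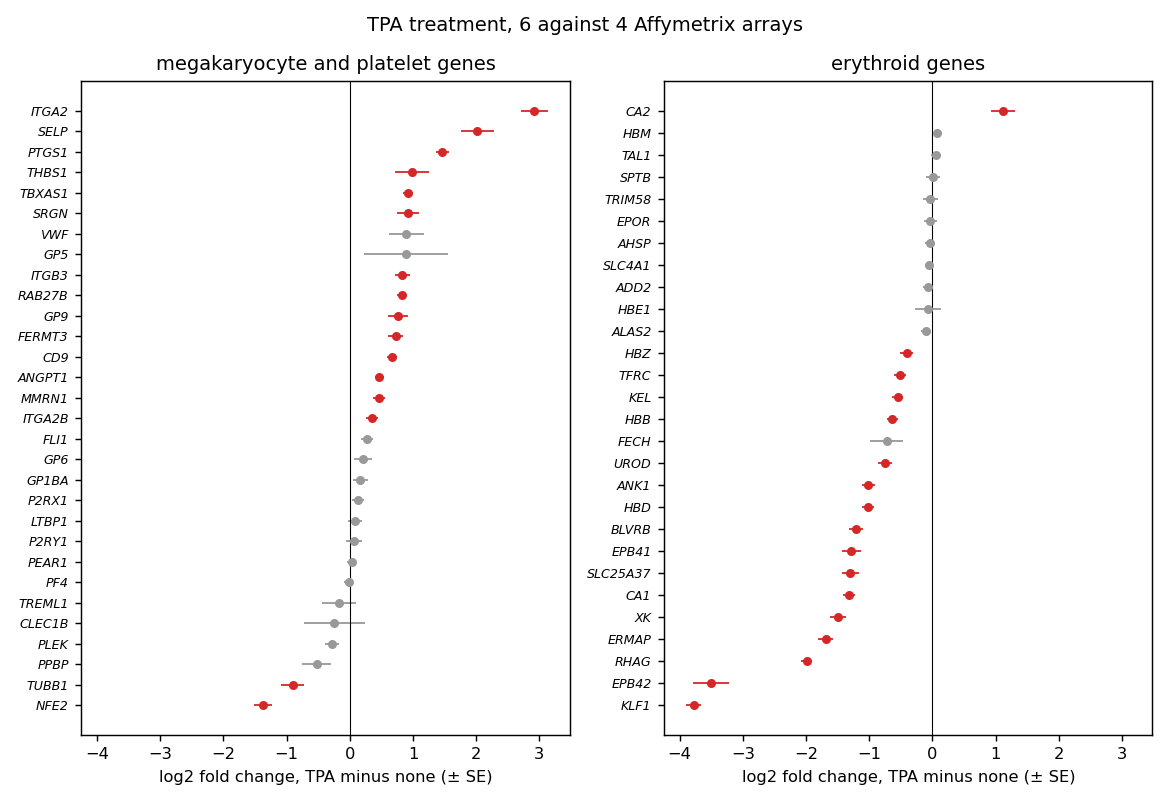
Log2 fold change with TPA over 6 arrays with and 4 without (horizontal axis, bars are SE) for 30 megakaryocyte and platelet genes and 28 erythroid genes (vertical axis), with genes that passed in red and the others in grey. Among the former 14 rose and 2 fell, and among the latter 1 rose and 16 fell.

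Further lists of signalling, adhesion and cell type genes were read for TPA. Immediate early genes rose in 15 of 17 members over all genes and adjusted over the list alone, with DUSP1 at 3.12 and EGR1 at 3.97 (camera adjusted p = 1.79e-14; adjusted p = 0.141 with an estimated correlation). AP-1 and phorbol ester response genes rose in 10 of 16 either way, with PLAUR at 4.01 and MAFF at 2.75 (camera adjusted p = 2.19e-07; adjusted p = 0.287 with an estimated correlation). SRF and MRTF cytoskeletal targets rose in 14 of 30 and 1 fell, or 17 and 1 adjusted over the list alone, with ACTN1 at 1.35, CCN1 at 2.58 and ITGA5 2.82-fold higher (camera adjusted p = 2.3e-07; adjusted p = 0.366 with an estimated correlation). The median of that list was 0.16 and 0.30 in control/HEL cells without and with doxycycline, and 0.58 and 1.42 in MKL1/HEL cells. Much of its rise thus came from the MKL1/HEL arrays. Integrin genes rose in 9 of 18 and 1 fell, or 10 and 1 adjusted over the list alone, with ITGA6 at 3.82, ITGB5 at 2.48 and ITGA4 at -0.91 (camera adjusted p = 4.04e-05; adjusted p = 0.0752 with an estimated correlation). Fibroblast and endothelial genes rose in 6 of 10 either way, with COL1A2 at 2.39 and TIE1 at 1.36 (camera adjusted p = 5.32e-05; adjusted p = 0.141 with an estimated correlation). Of 16 monocyte genes 4 rose and 1 fell either way, with FCER1G at 2.36, TLR4 at 1.91 and AIF1 at -0.32 (camera adjusted p = 0.0456; adjusted p = 0.366 with an estimated correlation). Of 14 lymphocyte genes GZMB, IL7R (2.64) and CD79B (0.61) rose and CD2 (-1.60) fell either way (camera adjusted p = 0.456), and the list's median of -0.04 and mean of 0.68 differed in sign.

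Cell cycle lists had negative medians with TPA. Mitosis genes fell in 14 of 31 members, or 24 adjusted over the list alone, with RACGAP1 at -1.07 and KIF11 at -1.21 (camera adjusted p = 2.36e-08; adjusted p = 0.385 with an estimated correlation). DNA replication genes fell in 5 of 34 either way, with TK1 at -0.91 and LIG1 at -0.61 (camera adjusted p = 3.82e-05; adjusted p = 0.478 with an estimated correlation; fry adjusted p = 0.138). The mitosis median was -0.26 and -0.33 in control/HEL cells without and with doxycycline, and -0.66 and -1.56 in MKL1/HEL cells. The DNA replication median was -0.26 and -0.28 in control/HEL and -0.37 and -1.38 in MKL1/HEL cells. Over all arrays these medians were -0.73 and -0.61, and without the MKL1/HEL doxycycline arrays -0.40 and -0.30. Ribosome biogenesis and MYC target genes fell in 6 of 21, or 9 adjusted over the list alone, with MYC at -1.18 (camera adjusted p = 2.76e-05; adjusted p = 0.385 with an estimated correlation). Their median was -0.17 and -0.14 in control/HEL cells without and with doxycycline, and -0.34 and -0.80 in MKL1/HEL cells.

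Metabolic and stress lists were also read for TPA. Of 19 cholesterol synthesis genes 6 fell and 2 rose, or 8 and 2 adjusted over the list alone, with LSS at -2.27 and STARD4 at 1.72 (camera adjusted p = 0.0291; adjusted p = 0.385 with an estimated correlation). Of 27 oxidative phosphorylation genes 3 fell, or 2 adjusted over the list alone (camera adjusted p = 0.0146; adjusted p = 0.388 with an estimated correlation). Of 21 interferon response genes 5 rose and 2 fell, or 6 and 2 adjusted over the list alone (camera adjusted p = 0.0303; adjusted p = 0.409 with an estimated correlation; fry adjusted p = 0.187). Their median was 0.08 and 0.10 in control/HEL cells without and with doxycycline, and 0.18 and 0.56 in MKL1/HEL cells. Unfolded protein response genes rose in 4 of 16 either way (camera adjusted p = 0.0271; adjusted p = 0.475 with an estimated correlation; fry adjusted p = 0.159). Their median was 0.56 and 0.50 in control/HEL cells without and with doxycycline, but 0.08 and -0.05 in MKL1/HEL cells. Of 23 hypoxia genes 8 rose, including NDRG1 (2.23) and the glucose transporter gene SLC2A3 (1.90), and 5 fell, including BNIP3L (-1.14), or 8 and 6 adjusted over the list alone (camera adjusted p = 0.128). Of 15 p53 target genes 4 rose, including CDKN1A (2.90), and 1 fell, or 5 and 1 adjusted over the list alone (camera adjusted p = 0.0775). Of 23 ATF4 response genes 4 rose, including DDIT4 (1.53), and 4 fell, including ASNS (-0.87), either way (camera adjusted p = 0.907). Of 10 heat shock genes HSPB1 (1.14) and BAG3 (1.02) rose either way (camera adjusted p = 0.548), with a list median of -0.04 and a mean of 0.09.

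MKL1 induction without TPA was read from 1 array with and 1 without doxycycline, with the spread of the duplicated groups. The largest differences by unadjusted p were those of ACTA2 (3.05, SE 0.35), ACTG2 (3.57, SE 0.41), GBP2 (1.66, SE 0.32), TPM2 (1.14, SE 0.26) and ITGB1BP2 (1.52, SE 0.44), and on the lower side DSPP (-0.84), STXBP5 (-0.57), NKAIN2 (-0.65), KCNJ14 (-0.63) and PIK3C2B (-1.02). None of these passed, each with an adjusted p of 1. No gene passed limma, and 12 had an unadjusted p under 0.05 where chance alone gives 760. The 30 SRF and MRTF targets had a median of 0.16, with 0 passing over all genes, 3 higher unadjusted and 2, ACTA2 and ACTG2, adjusted over the list alone (camera adjusted p = 7.24e-10; adjusted p = 0.975 with an estimated correlation). The test was hard to pass, since genes varied more between the duplicates, with an SD across genes of 0.382 and 0.373, than between these single arrays, at 0.151.

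Whether the response to MKL1 induction differed between TPA states was tested as an interaction. The difference of the doxycycline effects with and without TPA was 6.44 for SPRR2C (SE 0.33, adjusted p = 0.0234), 6.36 for TAGLN (SE 0.40, adjusted p = 0.0333), 5.96 for RPE65 (SE 0.39, adjusted p = 0.0333) and 4.21 for PLN (SE 0.30, adjusted p = 0.0368). Without TPA the doxycycline effects were -0.09, 0.38, 0.41 and 0.03, and in each gene both arrays with TPA and doxycycline lay above the other 8 arrays. SPRR2C, RPE65 and PLN had means under 5.46, the 40th percentile, in all other groups. They met the filter only through the MKL1/HEL arrays with TPA and doxycycline. On Illumina, with TPA, PLN differed by 1.04 without passing limma, and SPRR2C was not tested. GARIN1B, at 4.16, did not pass (adjusted p = 0.0658), but did with a filter at the 60th percentile (0.0346), with an intensity trend (0.000783) and without the first (0.00385) or the second (0.00745) array with TPA and doxycycline. The lowest unadjusted p among negative differences was that of TINAG, at -1.86 (adjusted p = 0.520). SPRR2C, TAGLN, RPE65 and PLN were all that passed of 15208, with 420 at an unadjusted p under 0.05 where chance alone gives 760. In the SRF and MRTF list 1 gene passed (camera adjusted p = 9.47e-12; adjusted p = 0.534 with an estimated correlation). Mitosis and DNA replication genes had median differences of -0.85 and -1.01, with 0 passing limma over all genes or adjusted over the list alone and 9 and 2 lower unadjusted (camera adjusted p = 5.54e-18 and 9.43e-12; adjusted p = 0.534 with an estimated correlation for both). With no filter 0 genes passed limma, and the lowest adjusted p of the 4 was 0.0735 for SPRR2C. PLN had an adjusted p of 0.0671 with the mean of all probe sets. With either array of TPA-treated MKL1/HEL cells lacking doxycycline left out 0 passed, without the first array with doxycycline 88, without the second 25, and with an intensity trend 15.

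Whether doxycycline acted differently in the lines under TPA was tested in the same way. The doxycycline effect in MKL1/HEL minus that in control/HEL was 6.76 for TAGLN (SE 0.40, adjusted p = 0.0257), 6.38 for SPRR2C (SE 0.33, adjusted p = 0.0249), 6.23 for RPE65 (SE 0.39, adjusted p = 0.0257), 5.76 for ACTA2 (SE 0.43, adjusted p = 0.0403), 4.18 for PLN (SE 0.30, adjusted p = 0.0384) and 4.11 for TPM2. In control/HEL cells the effect in these genes ranged from -0.02 for SPRR2C to 0.32 for ACTA2. Here too SPRR2C, RPE65 and PLN met the filter only through the MKL1/HEL arrays with TPA and doxycycline. No gene passed with a negative difference, where TINAG had the smallest p (-1.95, adjusted p = 0.367). These 6 genes passed limma of 15208, with 469 at an unadjusted p under 0.05 where chance alone gives 760. Among the 6 were 3 of the SRF and MRTF list (camera adjusted p = 1.15e-18, and adjusted p = 0.543 with an estimated correlation). With no filter 0 genes passed, and with the mean of all probe sets 3 did, without ACTA2 (adjusted p = 0.376) and PLN (0.0761). With either array of TPA-treated MKL1/HEL cells lacking doxycycline left out 0 passed, without the first array with doxycycline 109, without the second 36, and with an intensity trend 20.

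Doxycycline in control/HEL cells gave the background of the drug itself. The differences of smallest unadjusted p were those of HSD11B1-AS1 (0.54, SE 0.17), ZNF300 (0.61, SE 0.24), PDE2A (0.42, SE 0.16), KIR3DS1 (0.42, SE 0.16) and FMO5 (0.38, SE 0.16), and of CPA3 (-0.55, SE 0.18), DPPA4 (-0.41, SE 0.18), KRT80 (-0.35), CYP2E1 (-0.35) and FOXL2 (-0.38), none of which passed (adjusted p of 1). No gene passed limma, and 5 had an unadjusted p under 0.05 where chance alone gives 760. The comparison rests on 1 array per state in each TPA state, tested with the spread of other groups. Between the duplicates that gave this spread the SD across genes was 0.382 and 0.373. Between the control/HEL arrays with and without doxycycline it was 0.118 without TPA and 0.13 with TPA. The test was thus hard to pass, and the absence of calls does not show that the drug had no effect.

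The lines were also compared without doxycycline. DPPA4, a gene of pluripotent cells, was higher in MKL1/HEL than in control/HEL cells by 3.04 (SE 0.17, adjusted p = 0.0392), on each of 3 arrays against both control/HEL arrays. It alone passed limma, with 168 genes at an unadjusted p under 0.05 where chance alone gives 760. ACTG2 (2.39), GBP2 (1.65), CD2 (1.22) and ABCA17P (1.15) were the next higher genes and CPA3 (-1.24), TMEM132D-AS1 (-1.12), MIX23 (-0.88), HSD11B1-AS1 (-0.89) and S100A8 (at 0.499 of the control/HEL level) the lower genes of smallest p, and none of these passed (adjusted p of 1). DPPA4 failed with no filter (adjusted p = 0.102), with the mean of all probe sets (adjusted p = 0.718), and without the first (adjusted p = 0.320) or the second (adjusted p = 0.256) array of MKL1/HEL cells with TPA alone, where 0 genes passed. By camera 5 lists differed between the lines, with medians between -0.14 and 0.12 and none called with an estimated correlation (adjusted p = 0.890 to 0.942).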

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

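The tests of doxycycline itself, of the platform's probes, of equal response in both TPA states, of the amount of MKL1 RNA and of a shared day were chosen after the result was seen, and the others before.

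Differences between groups under the same treatment drew attention to 10 values. The doxycycline effect in MKL1/HEL cells with TPA minus that without was 6.44 for SPRR2C, 6.36 for TAGLN, 5.96 for RPE65 and 4.21 for PLN. The doxycycline effect under TPA in MKL1/HEL minus that in control/HEL was 6.76 for TAGLN, 6.38 for SPRR2C, 6.23 for RPE65, 5.76 for ACTA2, 4.18 for PLN and 4.11 for TPM2. Each was tested as an interaction by limma.

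MKL1 induction under TPA gave 85 genes higher and 4 lower on Affymetrix, against 904 and 755 at an unadjusted p under 0.05 and 363 and 282 without the first doxycycline array. Doxycycline itself is argued against, because the same genes, signed by direction, had a median change of 0.0078 in TPA-treated control/HEL cells against a median size of 2.59 in MKL1/HEL. Of 77 genes called on Affymetrix and tested on Illumina, 98.7 percent had the same sign there. This argues against probes of a single platform as the source of those calls. Signs of genes already called cannot show whether falls were missed on Affymetrix, so they do not test the imbalance itself. Illumina called 141 genes higher and 31 lower. Normalization to one distribution stays open as a cause of the imbalance: with Illumina arrays scaled to the same median the ratio of higher to lower calls was 1.37, and on the deposited values it was 0.337. The deposited arrays differ in median signal and all genes tested shifted by a median of -0.21, so the latter ratio alone does not decide. The Affymetrix values were normalized before deposit, so the ratio on them could not be tested. The imbalance may thus depend on scaling, and it was smaller at the unadjusted threshold and without that array, while an action of MKL1 as an activator also stays open.

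The 4 genes that responded more with TPA than without could have responded equally, the response without TPA being missed for want of replicates. The tables argue against this: the 10 largest rises with TPA, chosen without the arrays lacking TPA and holding all 4, had a median doxycycline effect of 5.37 with TPA and 0.20 without, on 1 array against 1, and in 9 of the 10 the latter was 0.56 or less. The tenth, ACTA2, was higher by 3.05 without TPA, on 1 array against 1 and without passing limma. Whether MKL1 was induced as far in cells with doxycycline alone is not known. Less MKL1 RNA after doxycycline without TPA cannot be told apart from a biological interaction, because the doxycycline difference of the brightest MKL1 probe set with TPA minus that without was -0.86 and the probe's place relative to the insert is unknown. The size of that value also depends on 1 array with TPA alone, at 9.39 against 8.45 in its duplicate.

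DNA replication genes were lower in replicate 2 than in replicate 1 of MKL1/HEL cells with TPA and doxycycline, by a median of -1.36 over 34 genes on Affymetrix. A fault of an Affymetrix array is argued against by the Illumina median of -1.15 from the same RNA, and a day or batch shared by all replicate 2 samples by a median of -0.0191 without doxycycline. Of 10000 random lists of matched expression 0 percent had a lower median, the lowest being -0.31. This argues against a loss that depends on abundance alone. Random lists were not matched on transcript lifetime, and the list was picked for its difference. Loss of short-lived transcripts was therefore not decided. Immediate early genes differed by 0.72 in the other direction, and by 0.44 without doxycycline. Mitosis genes also differed in the other direction, by 0.46 on Affymetrix and 0.48 on Illumina, so the cell cycle lists did not move as one. Replicates without doxycycline differed in mitosis genes by 0.27 and 0.25, so part of that difference was shared by samples without doxycycline. Another difference between the samples, such as the degree of induction, was not tested and stays open.

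Of 100 splits of the 10 arrays into 6 and 4, 1 called as many genes as TPA did, the real split with 3395, and the highest other called 56. This argues against a random division of these arrays but does not exclude chance. Only 100 splits were drawn, the others leave the TPA effect in their residual spread, and arrays may not be separate cultures. For MKL1 induction over both TPA states, the real split of the 6 MKL1/HEL arrays called 1 gene. Of the 10 splits, 2 called at least as many, the real split itself and 1 other. The highest other split called 35, and it set both arrays with TPA alone and the first with TPA and doxycycline against the rest. Both arrays lacking TPA lay on the same side of it. With TPA in the model, it therefore compared the second doxycycline array under TPA with the other arrays under TPA. The 35 genes thus read the difference of 1 induced array, and not a division free of treatment. With 10 splits the share cannot fall under 0.05.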

How the results depend on the processing

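TPA without the MKL1/HEL doxycycline arrays, the 60th percentile filter on Illumina and the lists without single arrays were alternatives chosen after seeing the data. Outside of leaving out arrays, named genes stayed on their side of the threshold in 700 cases, passed no longer in 43 and passed newly in 5. IKZF2 and, in the interaction with TPA, GARIN1B passed newly with the replicate number as a block (adjusted p = 0.0209 and 0.0181). For gene lists the numbers were 274, 100 and 4, with most calls ended by an estimated correlation or fry. With an array left out the numbers were 437, 60 and 3 for genes and 76, 4 and 4 for lists. No call among these turned its direction, but on Illumina the medians of the interferon, monocyte, integrin, lymphocyte and p53 lists changed sign with the scaling of the arrays. Of the counts per comparison and correlations, 51 stayed within their limits and 18 moved, and with an array left out 19 and 19.

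MKL1 induction with TPA on Affymetrix, 89 genes, gave 29 with no filter, 173 with an intensity trend, 379 (272 higher, 107 lower) with the replicate number as a block, and 1 over 6 MKL1/HEL arrays with TPA as a covariate. Leaving out arrays gave 8 to 645. On Illumina, 172 genes, the deposited values gave 1078, the trend 262 and the block 562. Leaving out arrays gave 0 to 1404. Replicates share only a number, and the difference of replicate 1 and 2 with doxycycline correlated with that without by 0.408 across genes on Affymetrix and 0.195 on Illumina, genes not being independent replicates. TPA, 3395 genes, gave 1774 with 8 group means, 5508 in control/HEL arrays and 1835 at 1.5-fold, and 1938 to 3644 without single arrays. The interaction with TPA, 4 genes, gave 0 with no filter, 15 with the trend, 7 with the block and 0 to 88 without single arrays. The interaction with the line, 6 genes, gave 0 with no filter, 3 with the mean of all probe sets, 20 with the trend and 0 to 109 without single arrays. The difference of the lines, 1 gene, gave 0 with no filter, 0 with the mean of all probe sets and 0 to 1 without single arrays. Leaving out an array of a duplicated group leaves 1 residual degree of freedom, the lone array being assumed to vary like the other pair, and a 1.5-fold minimum is a stricter rule. The comparison over 6 MKL1/HEL arrays fits 1 doxycycline effect to both TPA states, so a response seen only with TPA widens its residual spread. Why the other counts moved, up or down, was not tested. The correlation between platforms ranged from 0.765 to 0.805. Detection on all 4 Illumina arrays was not run. Signal over background limits folds, since 25 of 85 higher genes on Affymetrix and 20 of 141 on Illumina lay under the 40th percentile before induction.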

Other observations

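All 4 tests of this part were chosen after the result was seen.

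Several genes of muscle contraction were among those that rose with MKL1 induction under TPA. They were counted in a list written after the calls were seen, so the tests describe an overlap and cannot show that such genes rise as a group. On Affymetrix 10 of 53 listed genes rose against 75 of 15155 others (odds ratio 46.7, Fisher's exact test, two-sided, p = 2.77e-13), among them the sarcomere gene MYOM1, the calsequestrin gene CASQ1 and the kinase gene MYLK. On Illumina 13 of 41 rose (odds ratio 39.2, Fisher's exact test, p = 1.87e-15), with TNNC1, MYL4, MYL7 and the channel subunit gene KCNMB1. Without members of the SRF and MRTF list 4 of 43 (Fisher's exact test, p = 9.5e-05) and 7 of 31 (p = 9.96e-08) rose.

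The 85 genes raised on Affymetrix were also read in other groups. In MKL1/HEL minus control/HEL cells without TPA or doxycycline their median was 0.13, above the 95th percentile of 10000 random lists at 0.05. With doxycycline in MKL1/HEL cells without TPA their median was 0.0775, above the 95th percentile of 0.0321, and in control/HEL cells without TPA it was 0.0061, under that of 0.0186. Each median rests on 1 array against another, and random lists give the spread over genes, not over samples. The lists were matched on the mean over all 10 arrays, including those on which the 85 genes were called. Their members may therefore differ in level from the 85 genes on the arrays compared here. Expression of the insert without doxycycline therefore cannot be told apart from a difference between single arrays or between the lines. Nor can a smaller rise of the 85 genes as a set without TPA be told apart from a difference between single arrays. ACTA2, ACTG2, GBP2, TPM2 and ITGB1BP2, the genes of smallest unadjusted p among those higher without TPA, were all among the 85. They differed by 3.05, 3.57, 1.66, 1.14 and 1.52, where the SD across genes was 0.151. Each value rests on 1 array against 1, and none passed limma.

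It was asked whether MKL1 induction opposes part of the TPA response. The 31 genes that fell on Illumina had a median TPA change of -0.016 in control/HEL cells, which 70.5 percent of random lists lay below and which was under their 95th percentile of 0.04, so the genes as a set gave no sign of it. Members went both ways, and the median does not decide the question. Of the 31, 5 rose by over 1 with TPA in control/HEL cells (RFX6 4.24, ITGA2 3.40, HPSE 2.40, ST3GAL6 1.81 and CRYBA4 1.60) and 0 fell by as much. The share of all genes with such changes was not counted. A gene must also be expressed with TPA to be called lower there, so these counts do not decide the question either.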
